A study of Mus musculus with 16 samples.

How the data were processed

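Messenger RNA levels were measured on Illumina mouse BeadChips, glass arrays that read each probe as the mean light intensity of many beads, in 4 mammary tumour cell lines derived from HER2 transgenic mice. MI6 and MI7 carry d16HER2, a splice form of the HER2 receptor that lacks exon 16, and WTHER2-1 and WTHER2-2 carry the full-length (WT) receptor. Each line was hybridised to 4 arrays, which gave 16 arrays on 6 BeadChips. Per the labels' protocols, total RNA was extracted with Trizol, passed over a clean-up column with DNase, checked on a Bioanalyser and copied into biotin-labelled cRNA. The labels do not say whether the arrays of a line hold RNA of separate cultures. Where they do not, the p-values that use the spread between arrays measure technical spread.

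Each probe had a raw intensity on every array, which per the file headers is an average signal per probe, and which the authors deposited without normalization. BeadStudio is named in the submitters' processing notes, with no version. A detection p-value per probe and array, deposited beside the intensity per the file headers, ranks the probe among the negative control beads. The authors also deposited an intensity table on the linear scale whose arrays share 1 distribution of values, so it was quantile-normalized between arrays. That table was used as an alternative only. It nearly repeats the alternative with no background correction, which quantile-normalizes the raw intensities, so these are not separate checks. Median raw intensity ran from 83.5 on WTHER2-2 replicate 4 to 148.7 on WTHER2-1 replicate 3, and the share of the 45281 probes with a detection p under 0.05 from 35.8% on WTHER2-2 replicate 4 to 42.4% on WTHER2-2 replicate 1. Arrays give no counts, so their number limits the precision.

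Raw intensities were corrected for background with the normexp model of limma, which took the negative controls' distribution from the detection p-values, with an offset of 16 added, then quantile-normalized between arrays and put on the log2 scale. Quantile normalization gives every array the same distribution and removes a change shared by most genes. The offset pulls differences between dim probes towards 0. The work used R 4.3.3, limma 3.58.1 and statmod 1.5.0. Probes entered the tests when their detection p was under 0.05 on at least 4 of the 16 arrays, which 20152 probes did. The probe annotation paired 34885 probes with 1 gene symbol, 18 with several and 10378 with none. Of those with 1 symbol, 34807 matched a mouse gene table by gene ID, no symbol needed an update, and 5 symbols of the gene lists were found through older names. That table (assembly GRCm38.p6) was used for names only, so no coordinates are given. Each gene was represented by its brightest probe passing the filter, which left 10724 genes. Probes of this kind read a short stretch near the end of a transcript, so a gene's other probes can differ where transcript ends differ.

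The transgene was compared in 3 ways. The line-level test took the mean of each line's arrays and compared 2 lines with 2 in limma with an intensity trend in the variance prior, at a Benjamini-Hochberg adjusted p under 0.05. The second way described these 4 lines. A gene was called separated when all 4 pairs of a d16HER2 line and a WT HER2 line had the same sign, an adjusted p under 0.05 and an absolute log2 difference of at least 1 in a limma fit of the 4 lines to the 16 arrays. The third way was limma's camera test of gene lists on the line means, which compares a list with all other genes under a preset correlation between genes of 0.01. It covered the 29 lists with at least 5 measured members and was rerun with a correlation estimated for each list. An estimate from 4 line means is imprecise. Camera then also takes its degrees of freedom from those 4 means, which raises p even where genes are not correlated. MI6 was compared with MI7, and WTHER2-1 with WTHER2-2, in the fit of the 4 lines at the same thresholds as single pairs. The sum of squares over all genes was split into transgene, line and array parts. An exact two-sided permutation test of 2 lines against 2 cannot give a p under 0.333, so every p here rests on limma's model. The d16HER2 arrays shared BeadChips 1 and 2. Each WT HER2 line was on BeadChips of its own, so no BeadChip held both transgenes, and a difference between BeadChips cannot be told apart from one between transgenes.

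The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Erbb2, Egfr, Erbb3 and Erbb4, the 12 separated genes with the largest mean difference in each direction, up to 4 separated members of each list (or, where a list had none, the 2 members with the largest differences), the 5 largest genes in each direction for each pair of lines with the same transgene, and the 5 genes with the lowest p in each direction of the line-level test. Symbols that only number a predicted gene or clone were left out. Genes named outside this rule are marked as chosen after their values were seen. For called genes detected on at most 4 of the 8 arrays of the lower transgene, or 2 of the 4 of the lower line, a lower bound of the fold stands in place of the difference. Every fold is such a bound, with the undetected values of that side set to at least the dimmest detected value of their array. It bounds the difference between the means of the 2 transgenes, or of the 2 lines compared. A single pair of lines or arrays can differ by less.

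The alternatives were no background correction, a larger offset, median scaling, cyclic loess, the authors' normalized table, no detection filter, a stricter detection filter, the mean of a gene's probes, each array and each line left out in turn, other units of replication, BeadChip as a block, other variance priors, other fold minimums and an estimated correlation for the lists. Leaving out the WTHER2-2 arrays of BeadChip 4, or those of BeadChip 3, was added after seeing the data, as were the fits with the replicate number as a block. The line-level test, the rule for separated genes, the comparisons of 2 lines and the list test were run on simulated data. These were made from the measured means and spreads of the 10724 genes. The background correction, the normalization and the split of the sum of squares were not simulated. With the measured spread between lines, the line-level test found 37% of 100 genes changed 4-fold and 82% of those changed 16-fold, with 3 calls among unchanged genes. The rule for separated genes found 82% and 98%, with 62 calls among unchanged genes. The comparison of MI6 with MI7 found 93% and 98%, with 8 such calls, and that of WTHER2-1 with WTHER2-2 found 92% and 100%, with 2. The simulation gave all 4 lines the same spread between arrays for a gene, and drew the arrays independently. The measured WTHER2-2 arrays varied more, with 2235 genes at least 2-fold apart between its BeadChips against 29 in MI6. The rates found may therefore not hold for the measured lines. The test of the 29 lists called 0 lists when none was shifted and 1 when 1 list was shifted by 1.5 on the log2 scale. With an estimated correlation the list test called 0 in that simulation, so a list missed under that setting is not shown to be unchanged. The simulated genes varied independently of each other, while the epithelial list had an estimated correlation of 0.61. The simulation therefore does not show how often lists of correlated genes are called in error.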

Results

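Gene expression was profiled in 4 mouse mammary tumour cell lines to compare the transcripts of cells driven by d16HER2, the HER2 splice form that lacks exon 16, with those of cells driven by full-length WT HER2. MI6 and MI7 are the d16HER2 lines, and WTHER2-1 and WTHER2-2 the WT HER2 lines. Each line had 4 arrays, 8 per transgene and 16 in all. Values are background-corrected, quantile-normalized intensities on the log2 scale, given per line as mean ± SD over its 4 arrays, and differences are d16HER2 minus WT HER2 line means with the limma standard error. Every array measured 45281 probes and detected 35.8% to 42.4% of them, and 10724 genes were tested. Correlations between arrays of a line across genes, which are not independent replicates, were 0.977 to 0.997 in MI6, 0.976 to 0.994 in MI7 and 0.959 to 0.993 in WTHER2-1, but 0.852 to 0.991 in WTHER2-2.

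The difference between the d16HER2 and the WT HER2 lines held 42.4% of the sum of squares over all genes, lines of the same transgene 26.9% and arrays of the same line 30.7%. With 2 lines per transgene and no shared BeadChip, the first part cannot be credited to the transgene alone. The mean square was 3.63 between transgenes on 1 degree of freedom, 1.15 between lines on 2 and 0.219 between arrays on 12. MI6 and MI7 lay together on the first component, which held 47.8% of the variance, and away from both WT HER2 lines. The WT HER2 lines lay apart from each other on the second, which held 22.8%. WTHER2-2 split by BeadChip. Replicates 3 and 4, on BeadChip 4, differed at least 2-fold from replicates 1 and 2, on BeadChip 3, in 2235 genes, against 29 genes between the chips of MI6, 44 in MI7 and 214 in WTHER2-1. Without the WTHER2-2 arrays of BeadChip 4, a choice made after seeing the data, the share between transgenes was 51.7%.

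**Figure D1:**
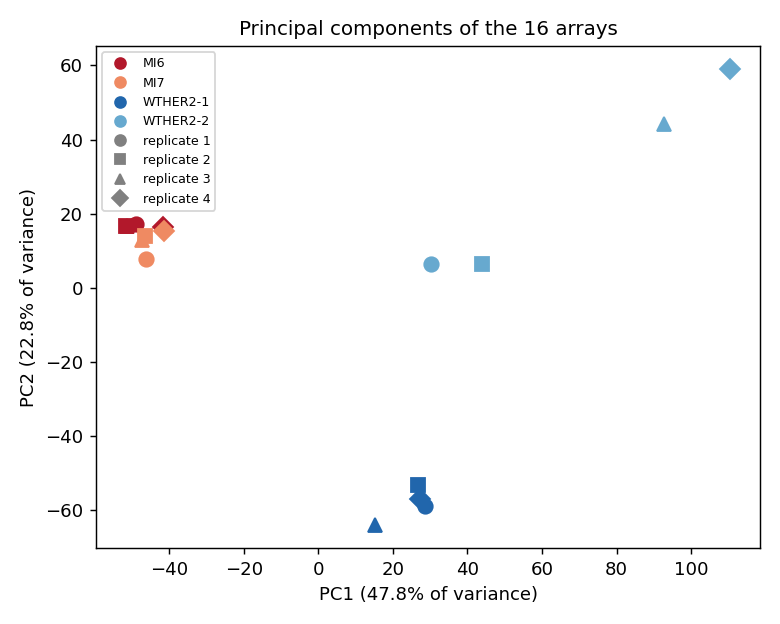
First and second principal components (47.8% and 22.8% of the variance) of the 16 arrays, coloured by cell line, with the marker giving the replicate. The arrays of MI6 and MI7 lie together, and replicates 3 and 4 of WTHER2-2, the arrays of BeadChip 4, lie apart from replicates 1 and 2.

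The d16HER2 lines carried high levels of genes that were far lower in the WT HER2 lines, some of them at or near background. Folds are lower bounds between the means of the 2 transgenes, so a single pair of lines can differ by less. Bricd5 measured 13.84 ± 0.47 in MI6 and 13.05 ± 0.15 in MI7 against 5.68 ± 0.16 in WTHER2-1 and 5.62 ± 1.5 in WTHER2-2, at least 175-fold more. Clic6, of the chloride intracellular channel family (5.72 ± 0.30 in WTHER2-1 and 7.26 ± 1.63 in WTHER2-2), was at least 80.3-fold higher. Sox10, a neural crest transcription factor also found in mammary progenitors, was detected on all 4 arrays of WTHER2-1 (9.31 ± 0.26) and on 1 of WTHER2-2 (6.29 ± 3.22), and was at least 47.2-fold higher (5.97 ± 1.08). Igfals, a subunit of circulating IGF complexes, and Foxi1, a forkhead factor of ion-transporting epithelial cells, were each detected on 1 of the 8 WT HER2 arrays, and were at least 54.6-fold and 27.5-fold higher. Conversely, Hp, which encodes the haemoglobin-binding acute phase protein haptoglobin, was at least 225-fold lower in the d16HER2 lines (5.53 ± 0.14 in MI6 and 6.68 ± 0.43 in MI7 against 13.41 ± 0.82 in WTHER2-1 and 14.54 ± 2.00 in WTHER2-2).

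In all, 592 genes were separated by transgene in all 4 line pairs, 328 higher and 264 lower in the d16HER2 lines. The other 2 ways to pair the 4 lines separated 12 and 11 genes. Each required MI6 to differ from MI7, which only 127 genes did, so these counts give no rate expected by chance. Other higher genes were the D-lactate dehydrogenase Ldhd (difference 5.37), the chitinase-like protein Chil1 (4.96), and, detected on at most 3 of the 8 WT HER2 arrays, the lipoxygenase Alox12e (at least 27.6-fold), the actin-associated Afap1l1 (31.5-fold, with a log2 difference of 1.64 at its other probe), the small GTPase Rasl12 (30.8-fold), the keratin Krt23 (30.3-fold) and the retinaldehyde dehydrogenase Aldh1a3 (21.6-fold). Lower genes included matrix and matrix-modifying genes, namely the collagen VI chain Col6a1 (at least 56.5-fold, with -5.64 and -1.39 at its other probes) and the lysyl oxidase Lox (25.8-fold), and the platelet-derived growth factor receptor Pdgfra (30.7-fold). They also included the small heat shock protein gene Hspb8 (-5.86), the surface antigen gene Ly6c1 (-5.73), Emp3 (-5.63), and, by at least these folds, Ecrg4 (44.5), the interferon-induced 2'-5' oligoadenylate synthetase Oas2 (32.7), the FGF-binding protein gene Fgfbp1 (26.3) and Rassf4 (27.3). Kng1, the kininogen gene, was detected on no d16HER2 array and was at least 23.1-fold lower (-1.77 at its other probe). Of the 592 genes, 81 were detected on no array of 1 transgene, 16 of them among the higher and 65 among the lower genes. On WTHER2-2 replicate 1, Sox10 measured 11.12 against 4.65 to 4.70 on the other arrays of that line, and Bricd5 7.85 against 4.66 to 5.15. Foxi1, Alox12e, Cxcr4 and Id4 were also highest there among the arrays of that line.

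**Figure D2:**
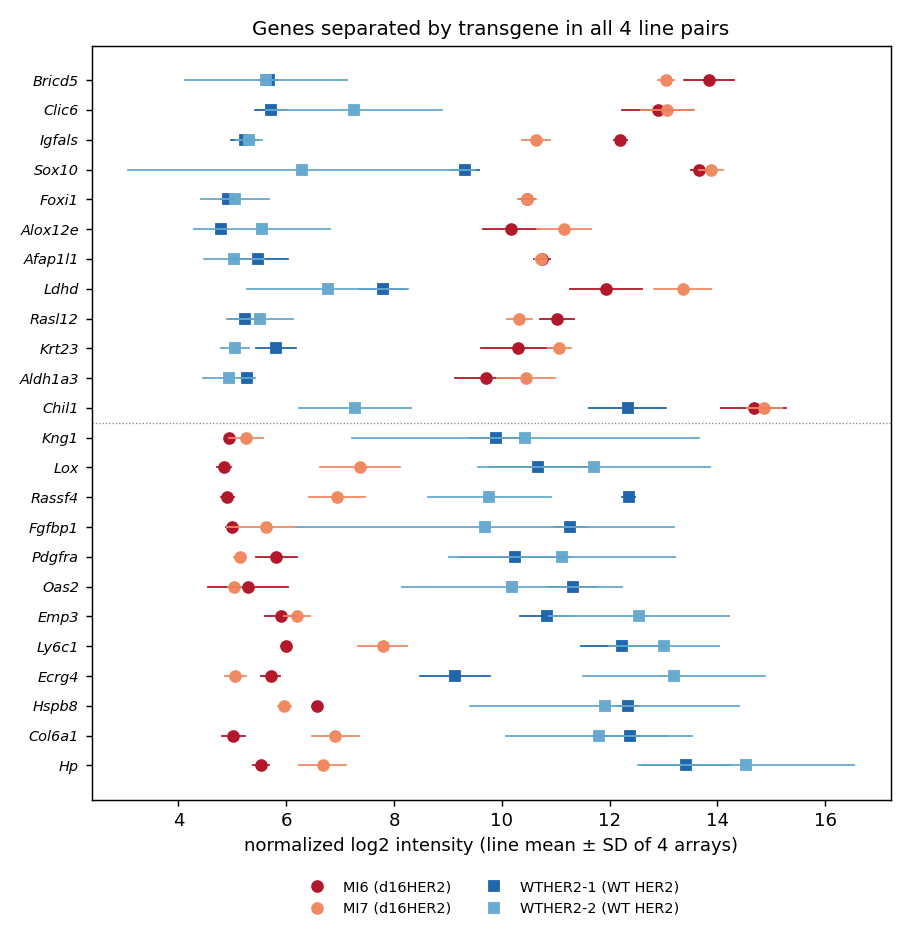
Normalized log2 intensity of the 12 genes with the largest higher and the 12 with the largest lower difference among those separated in all 4 line pairs, as mean ± SD of the 4 arrays of each line. Bricd5 lies at 13.84 and 13.05 in MI6 and MI7 and at 5.68 and 5.62 in WTHER2-1 and WTHER2-2, and the SD of WTHER2-2 is wide for many genes, 3.22 for Sox10.

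With the line as the replicate, 53 genes passed, 35 higher and 18 lower, and 52 of them were also separated. The exception was Meis2 (-3.12 ± 0.25, adjusted p = 0.0467), named after its values were seen. The lowest p-values of the higher genes belonged to the peptide transporter Slc15a2 (3.93 ± 0.16), the actin-bundling protein gene Espn (4.17 ± 0.19), the GABA-synthesizing enzyme Gad1 (at least 20.7-fold, with 1.86 and 4.40 at its other probes), Foxi1 and Bricd5, each with an adjusted p of 0.0399 in limma. Of the other detected probes of Espn, 1 differed by 3.87 and the rest by -0.08 and 0.41. Those of the lower genes belonged to the cyclin D2 gene Ccnd2, at least 16.2-fold lower, Hspb8 (-5.86 ± 0.33), the transcription factor Ebf3, at least 9.9-fold lower (-1.65 at its other probe), the apolipoprotein Apol9b (-4.08 ± 0.24) and Kng1, at the same adjusted p. With the mean of a gene's probes in place of the brightest, Espn (2.09) and Kng1 (-3.41) did not pass. Kng1 did not pass with no background correction either (-3.6). At an unadjusted p under 0.05, 2099 genes passed, against 81 and 89 for the other 2 pairings of the lines, of which 0 passed after adjustment in limma. Those pairings put the difference between transgenes into the residual spread. This keeps their counts low, so they give no rate expected by chance. The count of 53 was not stable. Without WTHER2-2 replicate 1, without replicate 2, without its BeadChip 4 arrays or without its BeadChip 3 arrays, limma called 0 genes (1982, 2032, 1967 and 1720 at an unadjusted p under 0.05), while the separated genes numbered 642, 627, 625 and 742. It was also 0 in limma with no detection filter, without MI6 and without MI7 (2565, 722 and 759 unadjusted), but 1542 without WTHER2-2.

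The ERBB receptors themselves did not separate the transgenes. The mouse Erbb2 probe measured 9.07 ± 0.10 in MI6, 9.19 ± 0.15 in MI7, 9.98 ± 0.23 in WTHER2-1 and 8.53 ± 0.99 in WTHER2-2, a difference of -0.13 ± 0.55. The probe was designed on the mouse gene, and the files do not say whether it reads the transgene, so it checks no label. Egfr differed by -0.27 ± 0.38 and Erbb3 by 0.29 ± 0.41, and Erbb4 did not pass the detection filter. Of the 17 measured ERBB receptor and ligand genes 0 were separated, with limma adjusted p = 0.966 for the list and 3 members at an unadjusted line-level p under 0.05. The largest differences were 1.52 ± 0.38 for the ligand Btc and 1.05 ± 0.83 for Epgn.

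As lists, epithelial genes lay higher and mesenchymal, fibroblast and, least steadily, protease genes lower in the d16HER2 lines under the preset correlation, though few members were separated. Of 28 epithelial junction and identity genes, 27 had a higher mean and 3 were separated, the junction protein gene Tjp3 (1.78 ± 0.33), the mucin Muc1 (1.66 ± 0.29) and the adhesion molecule Epcam (1.54 ± 0.22). With no background correction and in the authors' normalized table these 3 were not called (1.19, 0.94 and 0.87). The median difference was 1.31, with camera adjusted p = 8.47e-06, and adjusted p = 0.836 with an estimated correlation. Of 33 mesenchymal genes, 10 were separated and all 10 were lower, among them Lox, the collagen V chain Col5a1, at least 23.3-fold lower, the extracellular matrix protein Tgfbi, at least 14.6-fold lower (-2.28 at its other probe), and fibronectin Fn1 (-4.55 ± 1.36). The other 6, named after their values were seen, were the transcription factors Zeb1, Snai1, Snai2 and Twist2, the integrin Itga5 and the receptor Axl. On WTHER2-1 replicate 3 the list's mean was 7.36, against 8.43 to 8.55 on the other arrays of that line. The median difference was -1.77 (adjusted p = 5.6e-05, and 0.836 with an estimated correlation). Among 23 protease and invasion genes 9 had a higher mean and 2 were separated, both lower, and both encode protease inhibitors, Timp3 (-4.98 ± 1.28, with -0.67 and -1.93 at its other probes) and Timp2 (-1.73 ± 0.25). The list's median was -0.52 (adjusted p = 0.0289, and 0.836 with an estimated correlation). All 10 measured fibroblast markers had a lower mean, and Col6a1, Pdgfra, the actin-severing Gsn, at least 8.09-fold lower, and Col6a2, at least 4.89-fold lower (-1.43 at its other probe), were separated. Their median was -2.59 (adjusted p = 5.86e-05, and 0.836 with an estimated correlation). Adjusted over the list alone, 4 epithelial, 14 mesenchymal (3 of them higher), 1 protease and 4 fibroblast genes passed the line-level test, against 0, 1, 0 and 0 over all genes in limma (6, 18, 7 and 4 at an unadjusted p under 0.05). The BeadChip 4 arrays of WTHER2-2 moved with these lists. The epithelial mean was 10.21 and 10.04 on WTHER2-2 replicates 1 and 2 but 7.57 and 5.95 on replicates 3 and 4, and the fibroblast mean was 8.34 and 8.41 against 11.37 and 10.83. Without those 2 arrays the medians were 0.32 for the epithelial, -0.92 for the mesenchymal and -2.29 for the fibroblast list, all past the set test, and the protease list no longer passed (adjusted p = 0.173, range 0.000594 to 0.532 over its alternatives that keep the preset correlation). Without the line WTHER2-2 the mesenchymal list did not pass (adjusted p = 0.0664, range 1.03e-08 to 0.0664 over its alternatives that keep the preset correlation).

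**Figure D3:**
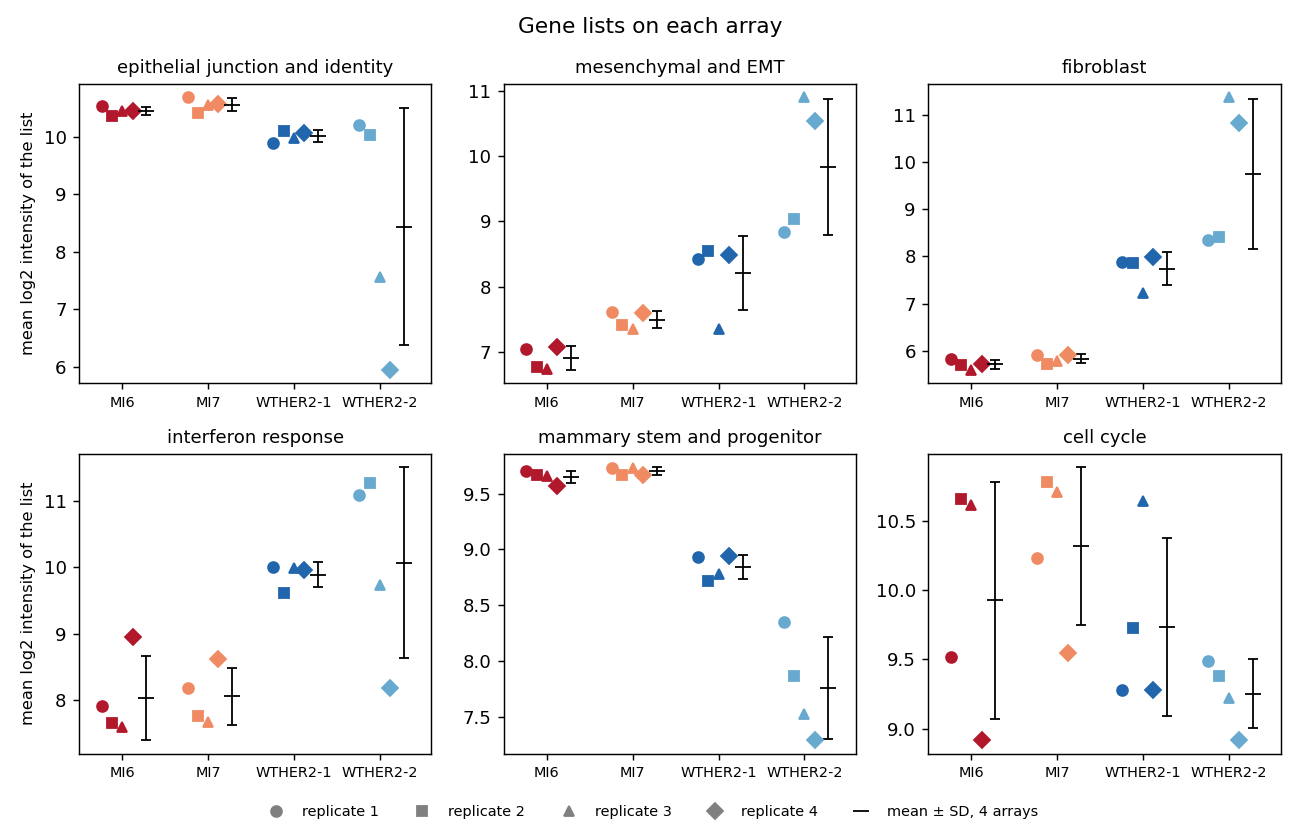
Mean log2 intensity of 6 gene lists on each array (points, marker by replicate) with the mean ± SD of the 4 arrays of each line (bars). The interferon list lies at or below 8.95 on every d16HER2 array, and the epithelial list lies at 7.57 and 5.95 on replicates 3 and 4 of WTHER2-2.

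Interferon response genes were lower in the d16HER2 lines as a group. All 32 measured members had a lower mean, 12 were separated, and the median difference was -1.79, with adjusted p = 3.16e-19 in limma's camera and adjusted p = 0.25 with an estimated correlation. That estimate was -0.0311, below the preset 0.01, so the rise of p does not come from the estimated correlation. An estimate from 4 line means is imprecise, so it does not show that these genes vary independently. Where they do not, the p under the preset correlation is too small. The separated members included the antiviral oligoadenylate synthetase family genes Oas2 (5.29 ± 0.74 in MI6 and 5.04 ± 0.12 in MI7 against 11.31 ± 0.45 in WTHER2-1 and 10.19 ± 2.04 in WTHER2-2), Oasl2 (-3.88 ± 0.34, with -1.87 and -3.05 at its other probes), Oas3 (at least 6.16-fold lower) and Oasl1 (-3.01 ± 0.42). Adjusted over the list alone, 27 members passed the line-level test, 0 of them higher, against 4 over all genes, namely Oas2 and, named after their values were seen, Isg15, Usp18 and Gbp3. On WTHER2-2 the list's mean was 11.10 and 11.28 on BeadChip 3 and 9.74 and 8.18 on BeadChip 4. Replicate 4 of MI6 and of MI7 lay above the other arrays of its line, at 8.95 and 8.61. Of 18 antigen presentation genes, the peptide transporter Tap1 (-1.64 ± 0.27) was separated and 5 had a higher mean. The median was -0.68 (adjusted p = 0.0138, and 0.836 with an estimated correlation), and 0 members passed the line-level test in limma over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05). This list did not pass without the BeadChip 3 arrays of WTHER2-2 (adjusted p = 0.0991) or without that line (0.714, range 1.44e-05 to 0.714 over its alternatives that keep the preset correlation).

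Mammary stem and progenitor genes were higher in the d16HER2 lines for 20 of 25 measured members, and 6 were separated as higher. The 4 largest were Sox10, Aldh1a3, the chemokine receptor Cxcr4 (9.38 ± 0.49 in MI6 and 9.51 ± 0.17 in MI7 against 5.23 ± 0.41 in WTHER2-1 and 5.14 ± 0.72 in WTHER2-2) and the transcriptional regulator Id4 (3.74 ± 0.56). The intermediate filament gene Nes (3.35 ± 0.52), named after its values were seen, and Epcam were the others. Id1 (-2.59 ± 0.81) and Klf4 (-2.16 ± 0.28, named after its values were seen), also members, were separated as lower. The median was 1.15 (adjusted p = 0.000401, and 0.836 with an estimated correlation). Adjusted over the list alone 10 members passed the line-level test, 9 of them higher, against 2 over all genes, Aldh1a3 and Cxcr4. The list's mean was 8.35 and 7.86 on BeadChip 3 and 7.52 and 7.29 on BeadChip 4 of WTHER2-2. Luminal and lactation genes (2 of 19 separated) included the folate receptor Folr1 (4.54 ± 0.34) and Muc15 (3.30 ± 0.74), and among 13 basal and myoepithelial genes the basal transcription factor Trp63 was at least 3.27-fold lower. Neither list passed (adjusted p = 0.64 and 0.999).

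Cell cycle genes had a higher mean in the d16HER2 lines for 31 of 34 members, with a median of 0.69 (adjusted p = 5.6e-05, and 0.836 with an estimated correlation), yet 0 members were separated and 0 passed the line-level test in limma over all genes or over the list alone (9 at an unadjusted p under 0.05). The centromere protein gene Cenpf differed by 1.37 ± 0.32 and the replication licensing gene Mcm3 by 1.35 ± 0.60. Arrays of a line differed as much. The list's mean ran from 8.92 to 10.66 in MI6, 9.55 to 10.78 in MI7, 9.28 to 10.64 in WTHER2-1 and 8.92 to 9.49 in WTHER2-2, lowest there on replicate 4 of BeadChip 4. Hypoxia and glycolysis genes were higher for 22 of 30 members, and 5 were separated as higher, the carbonic anhydrase Car12 (at least 12.2-fold), the phosphofructokinases Pfkp (2.68 ± 0.36) and Pfkl (1.29 ± 0.13, named after its values were seen), the prolyl hydroxylase Egln3 (1.53 ± 0.31, with 0.24 and 1.64 at its other probes) and the pyruvate dehydrogenase kinase Pdk1 (1.35 ± 0.25). The median was 0.37 (adjusted p = 0.00233, and 0.836 with an estimated correlation), and 8 members passed adjusted over the list alone against 0 over all genes in limma (11 at an unadjusted p under 0.05). The list's mean was 10.26 on WTHER2-1 replicate 3 against 11.01 to 11.11 on the other arrays of that line, and without that array Egln3 (1.33) and Pdk1 (1.16) lost their call. Of 21 p53 target genes 6 had a higher mean and 2 were separated, both lower, the microtubule-associated Psrc1 (-1.63 ± 0.24) and Phlda3 (-1.31 ± 0.19), an inhibitor of AKT signalling. That list's median was -0.47 (adjusted p = 0.00102, and 0.836 with an estimated correlation), with 7 members past the test adjusted over the list alone and 0 over all genes in limma (10 at an unadjusted p under 0.05).

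The signalling lists chosen for HER2 biology did not pass the set test, and most of their members were not separated. These were 21 of 23 Notch, 34 of 36 Wnt and 5 of 6 Hedgehog genes. They were also 22 of 23 MAPK, 21 of 23 PI3K and mTOR and 21 of 23 SRC genes. Among all tested genes with a symbol 5.52% were separated, so the few separated members of these lists mark none of them as changed. Among Notch genes (adjusted p = 0.55) the receptor Notch4 was higher by 2.91 ± 0.43 (1.25 at its other probe), and the brightest probe of the Notch inhibitor Numb was lower (-2.59 ± 0.39) while its other 4 detected probes differed by -0.02 to 0.27. Among Wnt genes (adjusted p = 0.64) the receptor Fzd5 was higher by 1.97 ± 0.26 (0.80 at its other probe) and Axin2, a feedback inhibitor, at least 2.21-fold lower. The Hedgehog list (adjusted p = 0.888) held Gli3 (-2.88 ± 0.63). MAPK output genes (adjusted p = 0.0653) had a higher mean for 18 of 23 members, with the phosphatase Dusp4 separated at its brightest probe (1.36 ± 0.21). Its other probes differed by 0.06, 0.41 and 0.49. The PI3K and mTOR list (adjusted p = 0.817) held the mTOR inhibitor Deptor (-2.09 ± 0.56, with -1.02 at its other probe) and the AKT phosphatase Phlpp1 (1.47 ± 0.32). The SRC and focal adhesion list (adjusted p = 0.341) held the kinase Fyn (at least 2.79-fold higher, with 0.10 at its other probe) and the integrin Itgav (1.32 ± 0.24, with 0.61 and 0.10 at its other probes). Chemokine and cytokine genes went both ways (adjusted p = 0.64, median 0.10 and mean -0.23). Of its 26 members 1 was separated as higher and 4 as lower, a larger share than among all genes, though the list did not pass. Ccl5 (-3.11 ± 0.23), Il18 (-2.88 ± 0.57) and Il34 (-1.83 ± 0.24) were lower and Csf3 higher (2.44 ± 0.39, with -0.16 at its other probe). The remaining separated member was Ccl25 (-1.71 ± 0.42), named after its values were seen. With the mean of a gene's probes in place of the brightest, Numb (-0.42), Dusp4 (0.58), Deptor (-1.55), Fyn (0.98), Itgav (0.68) and Csf3 (1.14) were not called, nor were Egln3 (1.14) and Tgfbi (-3.55) of the lists above.

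Among the other metabolic, stress and growth factor lists, none of which passed, NRF2 and glutathione genes (adjusted p = 0.921) held the aldehyde dehydrogenase Aldh3a1 (-4.72 ± 0.44), the glutathione transferase Gsta4 (2.63 ± 0.17) and the haem oxygenase Hmox1 (-2.02 ± 0.53). The unfolded protein and amino acid stress list (adjusted p = 0.726) held the serine synthesis enzyme Phgdh (-3.05 ± 0.43) and the fatty acid list (adjusted p = 0.888) the lipid droplet protein Plin2 (-1.30 ± 0.20). TGF-beta and BMP genes (adjusted p = 0.921) held Id1, Id3 (-2.25 ± 0.23) and the activin antagonist Fst (-2.04 ± 0.55), all lower. Angiogenesis genes (adjusted p = 0.341) held the semaphorin Sema3a, at least 6.57-fold lower, Sema3b, at least 4.02-fold higher (2.52 and 0.93 at its other probes), and Angptl4 (-1.93 ± 0.33). Of the cholesterol synthesis (adjusted p = 0.986) and cell cycle inhibitor (adjusted p = 0.503) lists 0 members were separated in limma (3 and 2 at an unadjusted line-level p under 0.05). The largest differences there were 1.09 ± 0.57 for Dhcr7, -0.88 ± 0.20 for Mvk, -1.59 ± 0.30 for Cdkn2a and -1.39 ± 1.61 for Cdkn2b. Adjusted over the list alone, the line-level test passed for 6 SRC and focal adhesion, 5 chemokine, 3 Notch, 3 NRF2, 2 Hedgehog, 2 angiogenesis, 1 luminal, 1 TGF-beta, 1 stress and 1 adipocyte gene, of which over all genes it passed for 1 chemokine (Ccl5), 1 NRF2 (Gsta4) and 1 luminal gene (Folr1). The median, the mean and the direction of the set test differed in sign for the Wnt (0.145, -0.04 and higher), Hedgehog (0.319, -0.05 and higher), ERBB (-0.06, 0.116 and lower), cholesterol (0.05, 0.07 and lower), TGF-beta (0.283, -0.08 and higher), chemokine (lower) and adipocyte (0.003, -0.319 and lower) lists.

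Few blood cell markers were detected. Of 12 lymphocyte markers with a probe 0 passed the detection filter, and of 16 myeloid ones 2 did, Aif1 (-0.27 ± 0.29) and Csf1r (-0.12 ± 0.21). The 6 measured of 13 endothelial markers (adjusted p = 0.565) included Plvap (-1.74 ± 0.96) and Eng (-0.81 ± 0.77), neither separated, and of 5 measured adipocyte markers (adjusted p = 0.817) the lipoprotein lipase Lpl was separated (-2.91 ± 0.47). The erythroid and muscle markers Mb (0.53 ± 1.07) and Des (-0.08 ± 0.21) were not separated. Xist differed by 0.46 ± 0.19 and Uty by 0.20 ± 0.23. Of 11 reference genes 0 were separated in limma (4 at an unadjusted line-level p under 0.05), with the largest differences in Tfrc (2.25 ± 0.70) and Actb (0.86 ± 0.14, between -1.22 and 0.63 at its other probes). Leaving out single arrays ended the separation of 24 named genes, namely Tjp3, Muc1, Epcam, Tgfbi, Trp63, Axin2, Phlpp1, Itgav, Tap1, Pdk1, Hmox1, Id1, Id3, Fst, Angptl4, Dusp4, Oasl1, Egln3, Phlda3, Il18, Il34, Sema3a, Col6a2 and Lpl, with no change of sign. With no background correction, and in the authors' normalized table, Tgfbi, Trp63, Axin2, Phlpp1, Fyn, Itgav, Tap1, Pdk1, Hmox1, Id3, Fst, Sema3b and Angptl4 were not called either, beside the 3 epithelial genes.

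MI6 and MI7, the d16HER2 lines, differed in 127 genes, 54 higher and 73 lower in MI6. The transcription factor Tfap2b (9.74 ± 0.23 in MI6 and 5.12 ± 0.18 in MI7, where it was not detected) and the CDK inhibitor Cdkn2b (11.88 ± 0.23 and 7.35 ± 0.38) were higher in MI6, by at least 17.4-fold and by 4.54 ± 0.90 (SE) on the log2 scale. The other 4 detected probes of Tfap2b were also higher in MI6, by 0.75 to 3.83. Sgip1 (4.32 ± 0.26), Nmral1 (3.93 ± 0.37) and the aldo-keto reductase Akr1c12 (3.52 ± 0.57) followed. The membrane metalloprotease Mmp14 (6.21 ± 0.28 in MI6 and 11.13 ± 0.28 in MI7), the caveolar protein Cavin3 (not detected in MI6, and at least 11.8-fold lower there), the iron-oxidizing enzyme Heph (-4.20 ± 0.24, with -3.70 to -1.61 at its other probes), Pxdc1 (at least 15.7-fold) and the crystallin Cryba4 (at least 12.8-fold) were lower in MI6. Both lines were present on BeadChips 1 and 2. In the 8 arrays of MI6 and MI7 alone, limma called 262 genes, and 263 with BeadChip as a block. With the replicate number as a block, a choice made after seeing the data, it called 319. Leaving out WTHER2-2 arrays, which set part of the pooled spread, moved the count to 255 without BeadChip 4 and 222 without BeadChip 3, and without MI6 replicate 3 it was 81. The calls of Cavin3 and Cdkn2b were lost without single arrays, and that of Cavin3 also with no background correction (-2.81) and with the mean of its probes (-3.45).

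WTHER2-1 and WTHER2-2 differed in 1702 genes, 876 higher and 826 lower in WTHER2-1. The surface antigen gene Ly6d measured 14.26 ± 0.53 in WTHER2-1 and 5.77 ± 0.76 in WTHER2-2, a difference of 8.49 ± 0.31 (SE). Them5 (not detected in WTHER2-2, and at least 45.2-fold higher, with 3.12 at its other probe), the placental hormone gene Prl2c4 (5.78 ± 1.14, with 7.32 on WTHER2-1 replicate 3 against 13.61 to 14.74 on the other arrays of that line), the basal keratin Krt14 (5.71 ± 0.90, with 10.49 and 10.62 on BeadChip 3 and 6.35 and 5.2 on BeadChip 4 of WTHER2-2) and the placental growth factor Pgf (5.68 ± 0.57) were also higher in WTHER2-1. The tight junction gene Cldn10 measured 4.84 ± 0.08 in WTHER2-1, where it was not detected, and 12.58 ± 2.07 in WTHER2-2, at least 131-fold more. Serpinf1 (at least 123-fold, with -0.79 at its other probe) and 3 small leucine-rich proteoglycans of the matrix, Ogn (at least 103-fold, with -3.12 and -4.11 at its other probes), Bgn (-6.69 ± 0.82, with 10.17 and 10.51 on BeadChip 3 and 14.83 and 14.37 on BeadChip 4) and Dcn (-6.64 ± 0.57), were lower in WTHER2-1. Erbb2 was higher in WTHER2-1 by 1.45 ± 0.34, with 9.43 and 9.33 on BeadChip 3 and 7.9 and 7.48 on BeadChip 4 of WTHER2-2. Erbb3, not detected in WTHER2-2, was at least 1.33-fold higher in WTHER2-1. The 2 lines shared no BeadChip. Without the BeadChip 4 arrays of WTHER2-2 the count was 1808, of which 1123 were among the 1702, and without its BeadChip 3 arrays 2554.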

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

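The tests of explanations in this part were chosen after the results they bear on had been seen, although the fit with no background correction had been planned as an alternative. Other splits of the arrays were counted first. In the 8 arrays of MI6 and MI7 alone, limma called 262 genes between the lines. Of the 35 splits of these arrays into groups of 4, 1, the real one, gave as many, and the highest other split gave 141. This would exclude chance only if the 8 arrays held separate cultures free of pairing. The labels do not say so. In deviations from the line mean, all 8 arrays correlated best with their own replicate number in the other line. Plain correlations did not all do so, since MI6 replicate 1 was closer to MI7 replicate 4 (0.9786) than to MI7 replicate 1 (0.9703). The highest other split set replicates 1 and 4 of both lines against replicates 2 and 3, which points to a structure of the samples that both lines share. If the number did pair the arrays, only 8 splits would part every pair, too few for a share under 0.05, where with a replicate block the real one gave 319 genes and the highest other 0 in limma (16 at an unadjusted p under 0.05 and 2-fold or more). Of the 35 splits of the WT HER2 arrays, 1, the real one, gave 1324 genes, and the highest other gave 0 in limma (at most 399 at an unadjusted p under 0.05 and 2-fold or more). This would exclude chance only if the arrays held separate cultures and those of a BeadChip were no more alike than others. Whole BeadChips allow only 3 splits there, too few for a share under 0.05. Arrays of a BeadChip were more alike in WTHER2-2 (r of 0.9914 and 0.9601, against 0.852 to 0.917 between its chips). In WTHER2-1 they were not clearly so (0.9881 and 0.9645, against 0.9585 to 0.9925 between its chips). The 4 lines make only 3 splits, too few for a share under 0.05. Of these, 1 split gave 53 genes in the line-level test, the real one, with 0 as the highest other in limma (89 at an unadjusted p under 0.05), and 1 split gave 592 separated genes, the real one, with 12 as the highest other. The other splits counted the difference between transgenes as spread in the line-level test. For separated genes they required MI6 to differ from MI7. Their counts were therefore low by construction.

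The WTHER2-2 arrays of BeadChip 4 stood apart from those of BeadChip 3, with 999 genes at least 2-fold higher and 1236 lower. Noise of single probes is argued against, since 91.9% of the 1202 other detected probes of these genes moved the same way, and so is dilution by 1 factor with cells that lack epithelial transcripts, since the falls of 9 bright epithelial genes ranged over 2.89 on replicate 3 and 3.68 on replicate 4 on the log2 scale, against at most 0.514 between replicates 1 and 2. For another of the 4 lines in their place, a first comparison left replicate 4 undecided (r of 0.852 to 0.857 with its own line and at most 0.834 with other lines, against 0.912 to 0.917 and 0.879 for replicate 3). A second test, chosen after that margin was seen, argues against it: of 135 probes detected on replicates 1 and 2 and on no array of another line, replicates 3 and 4 detected 61.5% and 41.5%, against at most 8.78% for an array of another line counted the same way. A culture in another state, a mixture with cells of other origin that keep some epithelial transcripts, and the BeadChip itself stay open, and no biological explanation was tested, since the labels give these arrays no difference.

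The interferon list was lower in the d16HER2 lines, with 30 of its 32 members lower in both d16HER2 lines than in both WT HER2 lines. Its highest d16HER2 array lay at 8.95 and its lowest WT HER2 array at 8.18, or 9.61 without BeadChip 4. The background correction as the whole cause is argued against by a median of -1.49 without it (camera adjusted p = 2.16e-19), and the BeadChip 4 arrays by a median of -2.43 without them (4.52e-19), over a range of adjusted p from 8.07e-24 to 3.21e-09 among the alternatives that keep the preset correlation. With an estimated correlation the list did not pass (camera adjusted p = 0.25). With 0 BeadChips that hold both transgenes, a difference between BeadChips cannot be told apart from one between transgenes, although the list differed between the chips of a line by at most 0.489 in MI6, MI7 and WTHER2-1 (and by -2.23 in WTHER2-2). A difference of the transgene, or of these lines apart from it, stays open and may not be separable with 2 lines each.

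WTHER2-2 replicate 1 held transcripts that were abundant in the d16HER2 lines. There were 90 genes at least 2-fold above replicate 2 on the same BeadChip. Of these, 90% were at least 2-fold higher in the d16HER2 lines than in the mean of both replicates. The share was 0% for the 10 genes below replicate 2 and 9.64% for all genes. A gene detected on neither replicate passed the detection filter only through other arrays, so 9.64% is no rate expected by chance. The contrast with the 10 genes, under the same filter, argues against noise that moves values both ways. Some of the genes were also high in WTHER2-1, such as Sox10 (mean 9.31). RNA of a d16HER2 line at 1 share is argued against as the source of all 19 abundant d16HER2 genes that replicate 2 did not detect, since at the best share and source, 5.6% of the RNA of MI7 replicate 3, 10 of them lay over 1 from the level needed on the log2 scale, and the farthest by 1.9. An earlier test set Sox10 (11.12 against 4.70 on replicate 2) and C2cd4a (11.31 against 4.63, named after its values were seen) apart by their shares (15.8% and 24.9%), which fixed part of its own result, so it was dropped. Such RNA behind part of the genes, and a difference between cultures, stay open.

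Single arrays far from the other 3 of their line were looked for in 616 groups of 4, of which 67 stood out (55 for genes and 12 for lists), against 30.8 expected, since chance marks about 1 group in 20. On WTHER2-1 replicate 3 the low values were 10.08 for Emp3, 8.68 for Pdgfra, 9.30 for Lox, 8.64 for Col5a1, 5.44 for Tgfbi, 11.51 for Fn1, 11.22 for Egln3, 8.32 for Fst, 6.73 for Sema3a, 8.16 for Lpl, 9.86 for Mb, 13.48 for Ly6d, 7.32 for Prl2c4 and 4.79 for Dcn. The high values there were 8 for Folr1, 9.98 for Mcm3, 8.22 for Hmox1 and 9.55 for Slc15a2. The mesenchymal (7.36), hypoxia (10.26), angiogenesis (8.57), fibroblast (7.22) and erythroid and muscle (7.80) lists were low on that array. On WTHER2-1 replicate 2 the interferon list (9.61) and the stress list (10.38) were low, and on replicate 1 Mvk (5.67).

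On WTHER2-2 replicate 1 the high values were 7.85 for Bricd5, 11.12 for Sox10, 5.98 for Foxi1, 7.45 for Alox12e, 6.22 for Cxcr4 and 6.56 for Id4. On its replicate 3, Axin2 was high (7.76) and Deptor low (9.72). On its replicate 4, Ecrg4 (10.68), Oas2 (7.15), Tfap2b (6.78), Cldn10 (9.50) and Ebf3 (6.08) were low, and Csf1r (6.82), Uty (6.01), the cholesterol list (10.43) and the stress list (11.23) high.

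On MI6 replicate 4, Clic6 (11.91), Sox10 (13.43), Afap1l1 (10.52) and Chil1 (13.78) were low, and Oas2 (6.39), Id4 (10.43), Oasl1 (7.73), Espn (12.95) and Ebf3 (4.73) high. On MI6 replicate 3, Ecrg4 (5.44), Aif1 (6.09), Mmp14 (5.78) and the adipocyte list (5.58) were low, and on replicate 1 Tfap2b (9.39). On MI7 replicate 4, Ldhd (12.57), Gli3 (5.25) and Angptl4 (5.91) were low, and Oas2 (5.22), Egln3 (13.68), Aif1 (6.30), Mb (10.75), Ogn (9.91) and the erythroid and muscle list (8.23) high. On MI7 replicate 1 the ERBB list was high (9.05). Among probes that no single gene symbol names, which no comparison used, 2989 passed the detection filter and 91 (3.04%) were separated in all 4 line pairs, 53 higher and 38 lower, against 5.52% of named genes.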

How the results depend on the processing

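Leaving out the WTHER2-2 arrays of BeadChip 4 or of BeadChip 3 and the fits with a replicate block were chosen after seeing the data, and all other alternatives before. The cause of a change was not tested unless given. The line-level count of 53 was the least stable. In limma it was 0 with no detection filter (2565 at an unadjusted p under 0.05, of 19057 genes), 0 without the BeadChip 4 arrays (1967), 0 without the BeadChip 3 arrays (1720), and 0 without cell line MI6 (722) and 0 without cell line MI7 (759), but 2439 without WTHER2-1 and 1542 without WTHER2-2, where the lone line was assumed to vary like the others. Counting arrays as replicates gave 1692 with the line as a random block, 1282 with BeadChip as a random block and 3787 as 8 against 8, by construction with more samples. Leaving out 1 array gave 0 (WTHER2-2 replicate 1 or 2) to 142 (WTHER2-1 replicate 3), with 84 without MI6 replicate 1, 113 without WTHER2-2 replicate 3 and 121 without replicate 4.

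The 592 separated genes became 409 with no background correction and 409 in the authors' normalized table, which nearly repeats that setting. They became 481 with the larger offset and 510 with BeadChip as a random block. Their number was 1293 with no fold minimum and 365 at a log2 difference of at least 1.5, and 534 to 642 without single arrays. The 127 genes between MI6 and MI7 became 77 with no background correction and 77 in the authors' normalized table, 255 and 222 without the BeadChip 4 and BeadChip 3 arrays of WTHER2-2, 262 in the 8 arrays alone and 263 with BeadChip as a block there, and 81 (without MI6 replicate 3) to 172 (without WTHER2-2 replicate 4) without single arrays. The 1702 genes between the WT HER2 lines became 1160 with no background correction and 1162 in the authors' normalized table. They became 1808 without the BeadChip 4 arrays, 2554 without the BeadChip 3 arrays, 3719 with no fold minimum and 1490 to 1949 without single arrays. Median scaling gave 1309 higher and 590 lower there, against 876 and 826. The share of variance between transgenes was 51.69% without the BeadChip 4 arrays (jackknife SE 6.8 percentage points) and 40.82% to 46.94% without single arrays. Replicate numbers were given here by the order of the arrays of a line, and the labels state no pairing. With them as a replicate block, the 8 arrays of MI6 and MI7 gave 319 genes (262 without it) and those of the WT HER2 lines 1017 (1324 without it). As a hint from the data, not the design, deviations from the line mean correlated by 0.228 to 0.687 between MI6 and MI7 arrays of 1 number, and all 8 correlated best with their own number, while 0 of the WT HER2 arrays did (-0.21 to 0.088).

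The count of 10 lists became 0 with an estimated correlation, 9 to 11 without single arrays and 7 to 12 without single lines, where the 11 and 12 include lists outside the 10. The epithelial, stem, cell cycle, interferon, hypoxia, p53 and fibroblast lists passed in all 31 alternatives that keep the preset correlation, the mesenchymal list in 30, antigen presentation in 29 and proteases in 24 (not without WTHER2-1 replicate 2, at 0.0601, or WTHER2-2 replicate 3, at 0.0698). MAPK output, not among the 10, passed in 7 of these 31, with adjusted p from 0.000366 to 0.714. Of 111 called values of named genes, 67 kept their call in every alternative, 44 lost it in at least 1, 36 of these without a single array, and 0 changed sign. Another 11 values became called. The median difference of all genes was 0.0276, and median scaling moved it to 0.096, more than the other scalings did. Dim genes limit the precision, since their differences shrink towards 0 at background.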

Other observations

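Cell cycle genes differed between arrays of a line in the same way in both d16HER2 lines, a pattern seen and described only after the data were examined and not tested for a cause. The list's mean was 9.52 and 8.92 on MI6 replicates 1 and 4 against 10.66 and 10.61 on replicates 2 and 3, and 10.23 and 9.55 on MI7 replicates 1 and 4 against 10.78 and 10.71 on replicates 2 and 3. Replicates 1 and 2 shared BeadChip 1 and replicates 3 and 4 BeadChip 2, so each chip held a lower and a higher array of each line. Other lists parted the same arrays. The interferon mean was 7.91 and 8.95 on MI6 replicates 1 and 4 against 7.65 and 7.59, and 8.18 and 8.61 on MI7 replicates 1 and 4 against 7.75 and 7.67. The cholesterol synthesis mean was 10.32 and 10.43 against 9.78 and 9.70 in MI6, and 10.44 and 10.37 against 10.06 and 10 in MI7. In WTHER2-1 the cell cycle mean was 10.64 on replicate 3 and 9.28 to 9.73 on the other arrays.

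MI6 replicate 2 and MI6 replicate 3, on different BeadChips, were the closest pair of arrays, with a median absolute difference of 0.12 on the log2 scale and 0 identical values, so they are not copies of 1 array. The basal and myoepithelial mean was 9.29 ± 0.45 (SD, n = 4) in WTHER2-1 and 7.86 ± 0.35 in WTHER2-2, with 8.27 ± 0.14 in MI6 and 8.77 ± 0.09 in MI7 between them, and the luminal and lactation mean was 10.49 ± 0.12 in WTHER2-1 and 8.83 ± 0.79 in WTHER2-2.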
